A study of Homo sapiens with 4 samples.

How the data were processed

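Poly(A) RNA was sequenced from H1 cells, an established human embryonic stem cell line carrying DUX4 under a doxycycline-inducible promoter. Per the labels, cells were transfected with a control siRNA (siNC, 2 libraries) or an siRNA against HNRNPU (siHNRNPU, 2 libraries). Doxycycline at 1 µg/ml followed 24 h later, and RNA was extracted 24 h after that. The kit did not keep the strand of the RNA, per the labels' protocols, so reads of a gene and of an antisense partner cannot be told apart. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

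The authors deposited whole-number read counts for 61822 rows, of which 60642 are genes by symbol and 1180 are repeat families. The authors also deposited TPM values for the same rows. In the deposited tables the ratio of count to TPM kept the same proportion between columns over 31411 rows, so the TPM values come from the same counts and are no independent measurement. Per the submitters' processing notes, FastQC 0.11.9, cutadapt 4.1, STAR 2.7.10a, featureCounts 2.0.1 and edgeR 3.30.3 were used with the human GRCh38 build; their settings are not given in the sources used here. How reads that map to several places were counted is not given either. That matters for repeat families and for genes with near-identical copies. As an example, the pseudogene EEF1A1P5 carried 218212 counts and EEF1A1 195494 in siNC replicate 1.

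Total counts per library were 49135337 and 48192754 for siNC, and 50335478 and 47492162 for siHNRNPU. The paired libraries of a group differed by more than Poisson sampling, with a chi-square per degree of freedom of 4.28 for siNC and 4.96 for siHNRNPU, so none was counted as a duplicate. The common biological coefficient of variation was 5.20%, and the median standard error of a log2 fold change was 0.13.

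The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes and repeat families were normalized and tested together with TMM factors, the default low-count filter (minimum count 10) and the quasi-likelihood test, siHNRNPU minus siNC. P-values were adjusted by the Benjamini-Hochberg method over all tested rows, and an adjusted p under 0.05 is called changed. A standard error is the log2 fold change divided by the square root of the F statistic. CPM values use the TMM factors and are given as mean ± SD (n = 2 per group). Of the tested gene rows, 94.21% matched 1 gene of GENCODE release 29 (GRCh38) by symbol. Coordinates and gene types are from that release, which may differ from the one the authors used.

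The design, the alternatives and 30 lists of genes or repeat families were fixed before the data were examined. The lists were DUX4 and 8-cell genes, primed pluripotency, naive pluripotency, trophectoderm and amnion, endoderm and mesoderm, neuroectoderm, fibroblast and matrix, hnRNP family, SR proteins and splicing kinases, nuclear lncRNAs, p53 targets, integrated stress and unfolded protein response, interferon response, immediate early genes, heat shock, S phase, mitosis, cohesin with CTCF and nuclear matrix, retroelement silencing, cytosolic ribosomal proteins, mitochondrial genome, replication-dependent histones, HERVL and MLT2, HERVH and LTR7, HERVK and LTR5, ERVL-MaLR, young L1, Alu, SVA, and satellites. TPRX2, CPHX1 and the satellites HSATII and SUBTEL_sa were not analysed here. Each list was tested with camera (limma 3.58.1), two-sided, with a preset correlation between members of 0.01 and adjustment over the 30 lists. An estimated correlation per list was the alternative. Camera then takes its degrees of freedom from the libraries instead of the tested rows. With so few libraries a list can hardly be called that way.

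Named genes followed a rule fixed with the design. HNRNPU and DUX4 were always named. Among changed genes with a mean of at least 5 CPM and no overlap between the groups' libraries, the 10 with the largest log2 fold change each way were taken. Each list gave up to 2 members each way with the smallest p; some members that the rule takes are not reported here. Among repeat families the 5 with the smallest p each way were taken, with 8 further families named in any case: MLT2A1, MLT2A2, HERVL-int, HERVH-int, LTR7, LTR5_Hs, HERVK-int and L1HS.

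The test was checked on simulated counts with the real means and library sizes for this comparison (26322 rows). It recovered 67.16% of genes changed 1.5-fold, 88.06% of those changed 2-fold and 100% of those changed 4-fold, with 2 false calls. None of 100 simulated lists without a shift was called, and 0 had an unadjusted camera p under 0.05. Simulated rows were drawn independently of each other, so false calls of lists whose members vary together were not tested. Alternatives were RLE, upper quartile and library-total scaling, no low-count filter or a mean of at least 1 CPM, the replicate number as a block, leaving out each library, and separate fits of genes and repeats. Further ones were DESeq2 1.42.0, the edgeR likelihood ratio test, and limma on log2 TPM with a pseudocount of 1 or 0.1 over rows with a mean of at least 1 TPM. A crossed block and a fit without mitochondrially encoded rows were added after seeing the data. When 1 library is left out, the lone library of its group is assumed to vary like the other group.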

Results

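The series asked which genes and transposable elements depend on HNRNPU, a nuclear RNA- and chromatin-binding protein, in human embryonic stem cells induced with DUX4. DUX4 is the transcription factor of the cleavage-stage embryo that pushes such cells toward a state resembling the 8-cell embryo. H1 cells received control siRNA (siNC, 2 libraries) or HNRNPU siRNA (siHNRNPU, 2 libraries) and all were treated with doxycycline. Total counts ranged from 47492162 to 50335478 per library. The first principal component held 91.55% of the variance and separated the siRNA groups. Repeat families took 16.1% and 17.03% of all counts in the siNC libraries and 21.4% and 20.3% in the siHNRNPU libraries.

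HNRNPU RNA was 3.16-fold lower after its siRNA, at 251 ± 3.91 CPM against 792 ± 12.6 CPM in siNC (mean ± SD, n = 2 per group; log2 fold change -1.66, SE 0.05; edgeR adjusted p = 9.13e-18). HNRNPU lies on chromosome 1 from 244840638 to 244864560, minus strand. DUX4, the induced factor, fell as well, from 269 ± 14.3 to 101 ± 17.96 CPM, which is 2.65-fold lower (log2 fold change -1.41, SE 0.08; edgeR adjusted p = 7.70e-13). Counts over 9 DUX4L genes annotated on chromosome 4, where DUX4 lies, were 16526 and 16271 in siNC and 6825 and 5325 in siHNRNPU. Over 14 DUX4L genes on chromosome 10 they were 19458 and 18628 in siNC and 7329 and 6520 in siHNRNPU. Reads of DUX4 and of these genes can be shared, and the tables do not say whether transgene reads were counted as DUX4.

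**Figure D1:**
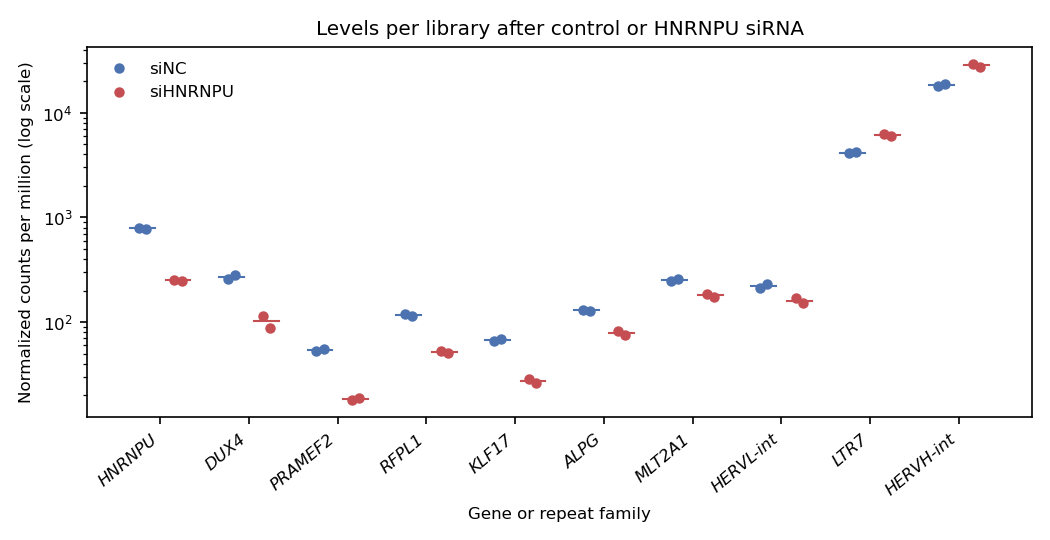
Normalized CPM (log axis) of HNRNPU, DUX4, 4 genes of the DUX4 and 8-cell list or naive list, and 4 repeat families, with 1 point per library and a short line at each group's mean. Both siHNRNPU libraries lie below both siNC libraries for HNRNPU (251 against 792 CPM), DUX4, the 4 genes, MLT2A1 and HERVL-int, and above them for LTR7 and HERVH-int.

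Of 25926 genes tested, 14808 changed: 7226 rose and 7582 fell after HNRNPU siRNA, and 2794 rose and 1869 fell at least 2-fold. Among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries, the largest rise was that of NOG, which encodes the secreted BMP antagonist noggin, from 0.17 ± 0.017 to 18.2 ± 0.847 CPM (103-fold; log2 fold change 6.69, SE 0.19; edgeR adjusted p = 1.53e-17). INSIG2, an endoplasmic reticulum protein that restrains sterol synthesis, rose 19.7-fold to 112 ± 1.83 CPM. SLC16A3, a lactate exporter, rose 19.2-fold to 85.9 ± 1.60 CPM. The liprin gene PPFIA4 rose 22.4-fold, the adhesion gene ICAM5 21.8-fold, the peptide ligand gene APLN 20.3-fold and the repressor gene BHLHE41 19.9-fold. UPK1A, AC092117.1 and the receptor gene EPHB3 rose 18.8-fold, 18.1-fold and 17.3-fold.

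Under the same limits, the gene with the largest fall was CER1, a secreted antagonist of Nodal and BMP, which was 15.3-fold lower, from 41.9 ± 2.93 to 2.73 ± 0.544 CPM (log2 fold change -3.93, SE 0.11; edgeR adjusted p = 6.45e-18). FLNC, which encodes the actin crosslinker filamin C, fell 8.17-fold from 516 ± 4.30 CPM. CAV1, a coat protein of caveolae, fell 10.2-fold and ANXA1 10.7-fold. SOX21, LIMCH1 and the BMP antagonist gene GREM1 were 11.9-fold, 11.4-fold and 10.5-fold lower. GCNT4, TWIST1 and CXCL14 were 9.27-fold, 9.26-fold and 8.59-fold lower. On the deposited TPM scale with limma and a pseudocount of 1, 7416 genes rose and 4029 fell (64.8% of calls higher, against 48.8% with the counts). The median of all genes was 0.13 in that fit, in which filter, scale and test all differed. Relative to siNC replicate 1, the ratio of count to TPM was 0.966 in siNC replicate 2. It was 0.883 and 0.859 in the siHNRNPU libraries, although total counts were similar. That scale by itself shifts log2 fold changes upward on TPM.

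**Figure D2:**
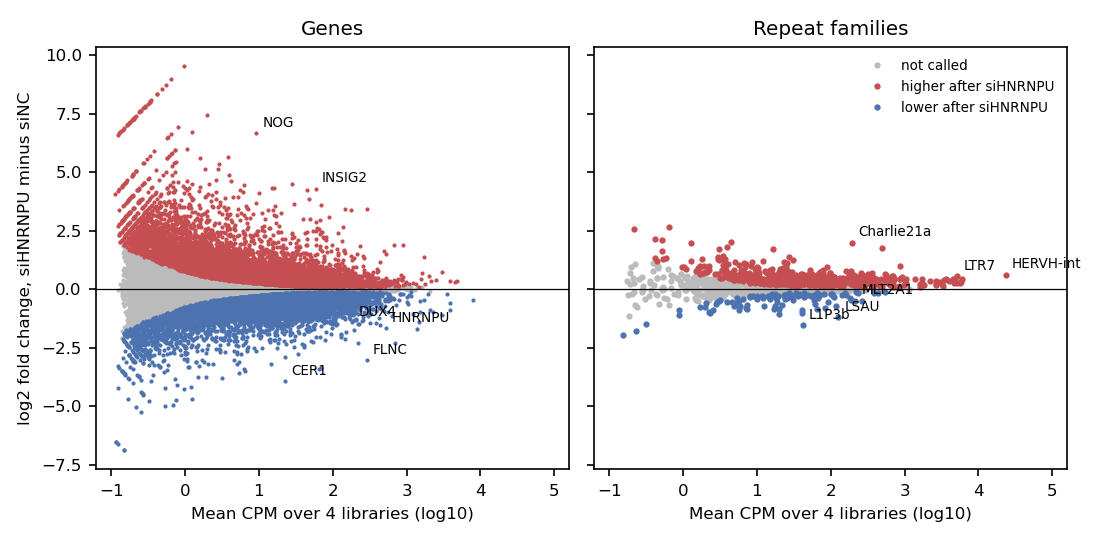
log2 fold change (siHNRNPU minus siNC) against the mean CPM over 4 libraries (log10) for genes and for repeat families, with 1 point per row, red where called higher, blue where called lower and grey where not called. NOG (6.69) and CER1 (-3.93) are among the labelled genes, and most called repeat families lie above 0 (552 of 666).

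DUX4 and 8-cell genes fell together. Of 41 measured members 36 fell, 2 rose and 3 did not pass the test, with the same counts when adjusted over the list alone, and the median log2 fold change was -1.001. PRAMEF2, a member of a cleavage-stage gene family, was 2.93-fold lower (53.5 ± 1.64 to 18.3 ± 0.558 CPM), and RFPL1 2.25-fold lower (117 ± 3.95 to 51.7 ± 1.71 CPM). PLD6 rose from 0.10 to 0.46 CPM and KHDC1 from 10.1 to 12.6 CPM, and both calls were lost without siNC replicate 1 (adjusted p = 0.051 for PLD6 and 0.40 for KHDC1) and without siHNRNPU replicate 1 (0.060 and 0.66). The PLD6 call was also lost without siHNRNPU replicate 2 (adjusted p = 0.062). The camera adjusted p of the list was 5.82e-28, and the adjusted p was 0.304 with an estimated correlation. Several members, PRAMEF2 among them, have near-identical copies whose reads can be shared.

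The HERVL and MLT2 list, chosen for the transcription of HERVL in DUX4-expressing and 8-cell-like cells, split. Of 18 families 5 rose, 5 fell and 8 did not pass the test. MLT2A1, the long terminal repeat of HERVL, fell 1.39-fold from 250.5 ± 6.84 to 179.6 ± 7.90 CPM (log2 fold change -0.48, SE 0.05; edgeR adjusted p = 3.27e-08), and HERVL-int fell 1.39-fold from 222 to 160.0 CPM. MLT2C2 and MLT2B3 rose with log2 fold changes of 0.52 and 0.22, and MLT2A2 did not pass the test (-0.09, SE 0.05). The list median was 0.01, the mean -0.06 and the direction of the camera test lower (adjusted p = 0.793). With repeats normalized and tested among themselves the list was called lower (median -0.21, camera adjusted p = 0.0029), MLT2A2 fell (-0.31) and MLT2B3 was no longer called (0.00080). That list call assumed the preset correlation of 0.01, whereas the estimate in the main fit was 0.46.

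The HERVH and LTR7 list was built around HERVH, a retroviral family transcribed in primed pluripotent cells. Its rows were grouped by name, and not each of them need mark that state. Of its 7 families 5 were higher and 1 lower (median 0.55, camera adjusted p = 0.0098, camera adjusted p = 0.397 with an estimated correlation). HERVH-int, the row with the most counts of all repeats named here, rose from 18506 ± 716 to 28526 ± 1223 CPM (1.54-fold) and LTR7 from 4143 ± 54.8 to 6134 ± 121 CPM (1.48-fold). HERVH48-int rose 2.16-fold, and LTR7Y fell 1.22-fold. On the TPM scale with limma, where 3 of the 7 families were tested, the HERVH and LTR7 call was lost (median 0.69, adjusted p = 0.364). LTR7Y was not called there either (-0.077). Normalized among repeats, the list's median was 0.32 (camera adjusted p = 0.011). In the HERVK and LTR5 list 6 of 21 families rose and 7 fell (median -0.07; camera adjusted p = 0.793). That median was -0.022 without siNC replicate 2, -0.027 without siHNRNPU replicate 2 and 0.23 on the TPM scale, where 4 families were tested. HERVK-int rose by a log2 fold change of 0.39 and LTR5_Hs by 0.23, whereas HERVK14-int (-0.83) and HERVK3-int (-0.45) fell. With repeats normalized among themselves LTR5_Hs was no longer called (0.01), and the HERVK and LTR5 list was called lower (median -0.29, camera adjusted p = 0.013). That list call assumed the preset correlation, whereas the estimate in the main fit was 0.086.

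Over all repeats, 666 of 1128 families changed, 552 higher and 114 lower, with a median log2 fold change of 0.23. Without siHNRNPU replicate 2 the counts were 561 higher and 74 lower, and without siNC replicate 2 555 and 83. Charlie21a, a DNA transposon, rose 3.998-fold (77.8 ± 0.566 to 311 ± 1.80 CPM), L1ME3C 3.36-fold, LTR82A 2.57-fold, LTR88c 2.38-fold and L1M2 1.98-fold. L1P3b fell 2.86-fold (61.8 ± 1.18 to 21.6 ± 0.994 CPM), MER52C 2.03-fold, LTR6B 1.83-fold (not called on the TPM scale, limma adjusted p = 0.077), MamGypLTR1b 1.78-fold and HERVS71-int 1.76-fold. With repeats normalized among themselves 341 families rose and 309 fell, so 52.5% of calls were higher against 82.9% beside the genes.

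Alu families rose, with 26 of 44 higher and 4 lower (median 0.18; camera adjusted p = 0.038, adjusted p = 0.887 with an estimated correlation). AluJo and AluJr4 rose 1.32-fold and 1.35-fold, and AluYm1 and AluYa5 fell 1.17-fold and 1.16-fold. The Alu call was lost without siNC replicate 1 (median 0.15, adjusted p = 0.17) and without siHNRNPU replicate 1 (0.14, 0.079), and the median turned to -0.04 with repeats normalized among themselves. Young L1 families gave 6 higher and 2 lower of 17 (4 and 1 adjusted over the list alone; median 0.06, camera adjusted p = 0.433). Leaving out 1 library put that median at -8.2e-05 (siNC replicate 1), 0.012 (siHNRNPU replicate 1), 0.13 (siNC replicate 2) or 0.12 (siHNRNPU replicate 2). L1PA8 rose by 0.67 and L1PA14 by 0.22 on the log2 scale, while L1PA12 (-0.18) and L1PA4 (-0.12) fell, and L1HS did not pass the test (0.04, SE 0.05). Normalized among repeats, the median of young L1 turned to -0.15 and was called lower (camera adjusted p = 0.0063), L1PA14 turned to -0.00068 and L1HS was called lower (-0.18, edgeR adjusted p = 4.1e-05). The young L1 call assumed the preset correlation of 0.01, whereas the estimate for its members in the main fit was 0.96. The calls of L1PA12 and L1PA4 were lost without siNC replicate 2 (-0.092 and -0.076) and without siHNRNPU replicate 2 (-0.12 and -0.065).

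ERVL-MaLR families gave 17 higher and 3 lower of 34 (median 0.16; camera adjusted p = 0.117), with MLT1L (0.50) and MLT1J (0.41) higher and THE1C-int (-0.72) and THE1C (-0.15) lower. That median turned to -0.064 with repeats normalized among themselves. Members of this list had an estimated correlation of 0.80 in the main fit, whereas its calls in other settings assumed the preset 0.01. The ERVL-MaLR list was called higher with no low-count filter (median 0.16, camera adjusted p = 0.0012), with a crossed replicate block (0.16, 0.044) and without siHNRNPU replicate 2 (0.20, 0.016). In the last of these THE1C was not called (-0.13), nor was it without siNC replicate 2 (-0.10). Of 6 SVA families SVA_B rose (0.72) and SVA_D fell (-0.48), while SVA_E (0.12) and SVA_C (-0.15) did not pass the test (median 0.04, turning to -0.18 among repeats and 0.020 without siNC replicate 1; camera adjusted p = 0.793). Normalized among repeats, SVA_E (-0.10, edgeR adjusted p = 0.042) and SVA_C (-0.38, 3.87e-06) were called lower. Satellites gave 3 higher and 5 lower of 16 (median -0.17; camera adjusted p = 0.503). LSAU, a satellite of the array that holds DUX4, fell 2.26-fold, SATR2 fell 1.37-fold, SST1 rose 2.23-fold, and (GAATG)n rose from 0.15 to 0.69 CPM, a call lost without siHNRNPU replicate 1 (log2 fold change 1.72, adjusted p = 0.105). Normalized among repeats, the satellite list was called lower (median -0.39, camera adjusted p = 0.0077). That call assumed the preset correlation, whereas the estimate in the main fit was 0.24.

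The lists of both pluripotent states were called lower, with members moving both ways. In the primed list 16 of 30 fell, 7 rose and 7 did not pass the test (median -0.22; camera adjusted p = 0.00083, adjusted p = 0.304 with an estimated correlation). PRDM14, a transcription factor of pluripotent cells, fell 4.73-fold and FGF2 2.90-fold, while DUSP6, a feedback phosphatase of ERK signalling, rose 3.18-fold and SFRP1 2.02-fold. Among core factors, named after their values were seen, SOX2 fell (-0.49, SE 0.05), whereas POU5F1 (-0.013, SE 0.049) and LIN28A (0.098, SE 0.047) did not pass the test. LIN28A was called higher without siHNRNPU replicate 1 (0.16, edgeR adjusted p = 0.0060). NANOG rose (0.21, SE 0.05), a call lost without siNC replicate 1 (0.15, edgeR adjusted p = 0.068). NANOG and POU5F1 have processed pseudogenes whose reads can be shared. On the TPM scale the primed list was not called (median -0.047, camera adjusted p = 0.156). In the naive list 14 of 20 fell and 1, DPPA2, rose 3.34-fold (median -0.92; camera adjusted p = 0.0015, adjusted p = 0.397 with an estimated correlation). KLF17 was 2.46-fold lower and ALPG 1.64-fold lower, and both are also in the DUX4 and 8-cell list; CPXM1 did not pass the test (0.16, SE 0.08). Without members shared with another list, the naive list was not called (median -0.83, adjusted p = 0.063), and on the TPM scale its median was -0.54 (camera adjusted p = 0.0034).

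Endoderm and mesoderm markers gave 12 lower and 5 higher of 20 (median -0.79; camera adjusted p = 0.00016, adjusted p = 0.304 with an estimated correlation). CER1 and LEFTY1, both antagonists of Nodal signalling, were 15.3-fold and 5.54-fold lower, whereas HHEX rose 29.6-fold from 0.26 to 7.65 CPM. Neuroectoderm markers gave 11 lower and 4 higher of 15 (median -0.95; camera adjusted p = 0.0045, adjusted p = 0.435 with an estimated correlation). The median was -0.62 without siNC replicate 1 (camera adjusted p = 0.017) and -0.44 on the TPM scale (0.012). NES fell 2.37-fold and TUBB3 1.93-fold, while RAX and SOX10 rose 4.46-fold and 1.85-fold at under 3 CPM. The SOX10 call was lost without siHNRNPU replicate 1 (0.67, adjusted p = 0.061). Fibroblast and matrix genes gave 13 lower and 4 higher of 21 (median -0.29; camera adjusted p = 0.0078, adjusted p = 0.444 with an estimated correlation). TAGLN fell 4.85-fold and VIM 1.89-fold, whereas LOX, a collagen crosslinking enzyme, rose 11.9-fold and CCN2 1.83-fold. The list's median was -0.53 with no low-count filter (camera adjusted p = 0.0016) and -0.11 on the TPM scale (0.046). Trophectoderm and amnion markers gave 7 lower and 3 higher of 16 (median -0.22; camera adjusted p = 0.793). Their median was -0.42 without siNC replicate 2, -0.39 without siHNRNPU replicate 2, -0.14 without siHNRNPU replicate 1, -0.43 with no low-count filter, -0.063 with a mean of at least 1 CPM and -0.053 on the TPM scale, and none of these was called. Of its members, TFAP2C was 2.11-fold and IGFBP3 2.61-fold lower, and the glucose transporter gene SLC2A3 was 2.58-fold and KRT19 1.27-fold higher.

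Transcripts of the mitochondrial genome fell. Of 15, 14 were lower and MT-RNR2, the large ribosomal RNA, was 1.27-fold higher (median -0.97; camera adjusted p = 4.0e-21, adjusted p = 0.304 with an estimated correlation). MT-ND1 fell 3.20-fold from 2085 ± 23.4 to 651 ± 9.39 CPM and MT-ND2 2.62-fold. All mitochondrially encoded rows together, in the list or not, took 4.45% and 4.44% of counts in siNC and 2.69% and 2.77% in siHNRNPU. Mitosis genes rose, with 20 of 29 higher and 2 lower (median 0.33; camera adjusted p = 6.42e-05, adjusted p = 0.304 with an estimated correlation). BUB1 and KIF2C rose 1.80-fold and 1.81-fold, and CDC20 and BIRC5 fell 1.16-fold and 1.13-fold. The BIRC5 call was lost without siNC replicate 1 (-0.15) and without siHNRNPU replicate 2 (-0.15), and neither was called on the TPM scale (-0.038 and -0.0047). S phase genes fell, with 19 of 27 lower and 3 higher (median -0.26; camera adjusted p = 0.0098, adjusted p = 0.444 with an estimated correlation), including CDC6 (1.96-fold) and CHAF1A (1.65-fold), while RRM1 and MCM6 rose 1.37-fold and 1.15-fold. On the TPM scale the S phase median was -0.088 (camera adjusted p = 0.046). Replication-dependent histones gave 7 higher and 1 lower of 18 (3 and 1 adjusted over the list alone; camera adjusted p = 0.1699, and 0.047, called higher, with no low-count filter). H2AC6 rose 3.92-fold to 13.5 CPM and H2BC21 4.80-fold to 7.39 CPM, H2BC9 fell 1.25-fold and H2AC18 did not pass the test (-0.38, SE 0.20). Poly(A) RNA was sequenced, so histone transcripts without a poly(A) tail are largely missing from these counts. The H2BC9 call was lost without siNC replicate 1 (-0.27) and without siHNRNPU replicate 1 (-0.19).

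Lists of RNA-binding and nuclear proteins held members moving both ways and none was called. Of 29 hnRNP genes 9 rose and 11 fell (camera adjusted p = 0.433), with HNRNPH3 1.94-fold and HNRNPUL2 1.44-fold higher and HNRNPD 1.69-fold lower. Of 26 SR proteins and splicing kinases 9 rose and 12 fell (camera adjusted p = 0.169). The kinase genes CLK3 and CLK4 rose 2.23-fold and 2.14-fold, and SRSF6 and SRSF2 fell 2.27-fold and 2.06-fold. Nuclear lncRNAs gave 12 higher and 9 lower of 23 (camera adjusted p = 0.342), with MALAT1 2.90-fold and NEAT1 1.84-fold higher and LNCPRESS1 2.57-fold and SNHG12 1.78-fold lower. Cohesin, CTCF and nuclear matrix genes gave 8 higher and 11 lower of 27 (9 and 11 adjusted over the list alone; camera adjusted p = 0.323), RAD21 and AKAP8L being 1.41-fold and 1.40-fold higher and LMNA and LBR 2.43-fold and 1.67-fold lower. Retroelement silencing genes gave 8 higher and 16 lower of 25 (camera adjusted p = 0.204). CBX5 rose 1.46-fold and ATF7IP 1.45-fold, while the DNA methyltransferase gene DNMT3A fell 2.01-fold. Cytosolic ribosomal protein genes gave 9 higher and 5 lower of 50 (8 and 5 adjusted over the list alone; median 0.0066, from -0.066 to 0.099 when 1 library was left out; camera adjusted p = 0.835). RPL15 and RPL4 rose 1.30-fold and 1.19-fold, and RPL9 and RPL35 fell 1.61-fold and 1.21-fold. On the TPM scale the medians of the hnRNP, SR protein and cohesin lists turned from -0.039, -0.079 and -0.040 to 0.13, 0.089 and 0.12, and cytosolic ribosomal proteins were called higher (median 0.17, camera adjusted p = 0.0066).

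Among stress lists, integrated stress and unfolded protein response genes gave 14 lower and 6 higher of 26 (median -0.39; camera adjusted p = 0.029, adjusted p = 0.593 with an estimated correlation). The amino acid genes SLC7A11 and PSAT1 fell 2.84-fold and 2.22-fold, whereas DDIT4, an inhibitor of mTORC1 signalling, rose 10.96-fold from 48.0 ± 2.66 to 526 ± 20.6 CPM and VLDLR 2.14-fold. That list's call was lost without siHNRNPU replicate 1 (median -0.37, camera adjusted p = 0.11), with a mean of at least 1 CPM (-0.37, 0.091), on the TPM scale (-0.21, 0.11) and without members shared with another list (-0.39, 0.063). p53 targets gave 14 higher and 9 lower of 28 (camera adjusted p = 0.077), BTG2 rising 10.3-fold and SESN1 2.88-fold while PLK2 fell 2.58-fold and SESN2 2.03-fold. That list was called higher without siHNRNPU replicate 1 (median 0.25, camera adjusted p = 0.026), with upper quartile scaling (0.25, 0.049), with genes fitted apart from repeats (0.22, 0.048) and without members shared with another list (0.25, 0.028). Interferon response genes gave 4 higher and 5 lower of 25 (camera adjusted p = 0.793), with IFITM1 and BST2 1.73-fold and 1.63-fold higher and OAS3 and MX1 3.58-fold and 2.16-fold lower. Heat shock genes gave 6 higher and 12 lower of 24 (camera adjusted p = 0.203), with HSPA4L 3.296-fold and HSF2 2.07-fold higher and DNAJA1 2.06-fold and HSPA1B 1.96-fold lower. Immediate early genes gave 9 higher and 5 lower of 24 (camera adjusted p = 0.498), with KLF10 1.84-fold and NR4A1 1.67-fold higher and FOSL1 2.09-fold and MYC 1.61-fold lower. In total 12 of the 30 lists were called, 3 higher and 9 lower. With an estimated correlation 0 were called by camera, 4 having an unadjusted p under 0.05. That setting can hardly call a list with so few libraries, so it decides little about a list either way.

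**Figure D3:**
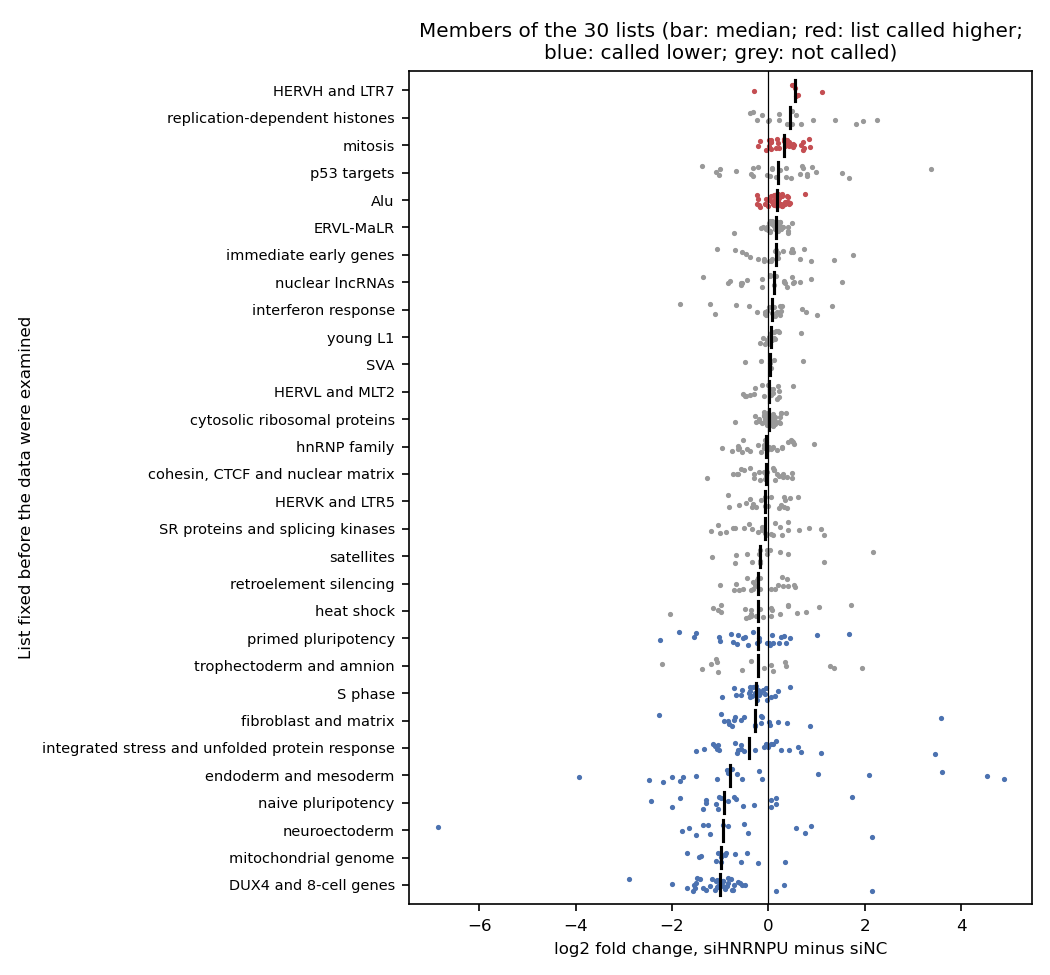
log2 fold change (siHNRNPU minus siNC) of each measured member of the 30 lists, with 1 point per gene or repeat family and a bar at each list's median, red for lists called higher, blue for lists called lower and grey for lists not called. DUX4 and 8-cell genes have the lowest median (-1.001) and HERVH and LTR7 the highest (0.55); medians of ERVL-MaLR, young L1, Alu and SVA turn below 0 with repeats normalized among themselves.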

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

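The crossed block and the fit without mitochondrially encoded rows were chosen after the result was seen. HNRNPU and the DUX4 and 8-cell list stayed lower in every alternative run, with log2 values from -1.68 to -1.46 and from -1.02 to -0.83; only the estimated correlation ended the list's call (median -1.001, adjusted p = 0.304). That setting left 0 of the 12 called lists. For primed pluripotency (-0.033), endoderm and mesoderm (-0.0016) and HERVH and LTR7 (-0.077) the estimated correlation lay below the preset 0.01. A higher correlation therefore does not account for the loss of these calls. The other called lists had estimates from 0.015 (mitosis) to 0.66 (Alu). For mitosis the estimate was close to the preset, yet the unadjusted camera p went from 6.42e-06 to 0.0506. With an estimated correlation camera takes its degrees of freedom from the libraries instead of the tested rows, which by itself raises p. How much of each loss came from the correlation was not tested. Requiring a 2-fold change left 4663 genes and 47 repeat families. On TPM 13 of 76 repeat families were called with either pseudocount; filter, scale and test changed together, and the cause was not tested. With genes and repeats fitted separately, centring moved repeats down: the HERVL and MLT2 list became called at -0.21, and L1PA14 (-0.00068), SVA_E (-0.10), L1HS (-0.18), ERVL-MaLR (-0.064), young L1 (-0.15), Alu (-0.042) and SVA (-0.18) turned negative, with SVA_E, L1HS and young L1 called lower. List calls among repeats assumed the preset correlation, although the main fit gave estimates of 0.96 for young L1 and 0.46 for HERVL and MLT2. On TPM the hnRNP family (0.13), cohesin with CTCF and nuclear matrix (0.12) and HERVK and LTR5 (0.23, 4 families tested) turned positive. The median of all genes there was 0.13, or 0.16 with a pseudocount of 0.1, against -0.0054 in the main fit. Without shared members retroelement silencing (-0.18) changed its test direction; the cause was not tested. Leaving out 1 library gave ranges of -0.12 to 0.11 for the median of HERVL and MLT2 (0.11 without siHNRNPU replicate 2, where the test direction turned to higher, and below 0 without each other library), -8.2e-05 to 0.072 for L1HS and -0.066 to 0.099 for cytosolic ribosomal proteins, none of them called.

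The replicate number as a block gave 14236 genes, 640 repeat families and 11 lists, losing Alu (0.18, adjusted p = 0.065) and L1PA4 (-0.12, 0.12); HNRNPU stayed at -1.66, the DUX4 and 8-cell list at -1.01 and HERVL and MLT2 at 0.0085. Nothing shows that the numbers pair the libraries, and deviations of same-numbered libraries correlated at -0.10. A crossed block gave 15427 genes, 707 families and 13 lists. Of 151 named genes and families 145 were called. Of these, 129 were called in every alternative run that tested them, and 1 called family turned its direction. Rows that a filter removed from a run were not judged in it, and on TPM only 76 repeat families were tested. With 2 libraries per group, 1.5-fold changes were recovered in 67.16% of simulated cases. In that simulation 26122 of 26322 rows were unchanged, whereas 14808 of 25926 genes were called here. The rate need not hold for the real data, and small changes can still be missed.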

Other observations

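The tests of the DUX4 pattern and the test on raw repeat shares were chosen after the result was seen, and the lists in this part were written after the ranked genes had been seen. Genes induced by hypoxia-inducible factors were higher after HNRNPU siRNA: of 25 such targets 23 rose, with a median log2 fold change of 1.90 (camera adjusted p = 6.85e-68 over the 30 fixed lists and these 5). With an estimated correlation none of the 35 lists was called, and the adjusted p of the HIF targets was 0.253 (unadjusted p = 0.0149). EGLN1, an oxygen sensor, rose 7.77-fold, BNIP3 6.402-fold, the glucose transporter gene SLC2A1 3.71-fold and PDK1 4.51-fold, whereas CA9 (0.39, SE 0.52) and EGLN3 (0.01, SE 0.06) did not pass the test. All 15 glycolysis genes measured were called higher (median 0.65; camera adjusted p = 2.65e-17, adjusted p = 0.269 with an estimated correlation), from PGK1 at 3.74-fold and LDHA at 2.87-fold to PKM at 1.08-fold.

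Targets of YAP and genes of the contractile cytoskeleton were lower, 15 of 22 falling and 3 rising (median -0.85; camera adjusted p = 3.57e-10, adjusted p = 0.253 with an estimated correlation). TPM1 fell 2.46-fold, MYL9 2.32-fold, THBS1 2.25-fold and AXL 2.04-fold, while CCN2 rose 1.83-fold. TAGLN, CCN1, CCN2 and ACTA2 are also in the fibroblast and matrix list, whose values had been seen. Cholesterol synthesis genes gave 8 higher and 12 lower of 22 (median -0.16; camera adjusted p = 0.835), with STARD4 2.94-fold higher and LSS 1.87-fold lower.

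The rise of oxygen and glycolysis genes may reflect a hypoxia-type programme. The median of the HIF targets was 1.90 (bootstrap 95% interval over genes 0.93 to 2.37), on a list written after the ranked genes had been seen. That median describes the rise and does not separate such a programme from other causes. A GC content bias is argued against, since the median stayed at 1.95 after removing the trend on transcript GC and length (24 genes). A fall of respiratory chain RNA that extends to nuclear-encoded genes is argued against by 24 such members, whose median was -0.020 (-0.18 to 0.026). These nuclear-encoded members moved both ways, with 6 called higher and 9 lower. Mitochondrially encoded transcripts did fall, 14 of 15 being lower (median -0.97). Whether that fall is linked to the rise of glycolysis genes was not tested. A difference in wells or handling between the groups cannot be told apart from the siRNA, because the labels name no culture or day apart from the siRNA group; libraries of a group differed by a median of only 0.079. Measuring the same genes in independently plated wells would decide this. Lower DUX4 RNA cannot be told apart from lower HNRNPU here either, as both fell in the same libraries and all were treated with doxycycline. That limit holds for every difference between the groups.

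The fall of the DUX4 and 8-cell genes is not explained by reads shared between copies alone. In a search with blastn 2.17.0, 10 of the 40 members in GENCODE 29 had no stretch of at least 100 bases at 95% identity in a transcript of another gene; their median was -0.94 (-1.14 to -0.73), and 9 of them were called lower. Nor is it a shift of all genes at such levels, since 0 of 10000 random lists matched on CPM had a median as low (-0.39 to 0.33). Lower DUX4 RNA (-1.41, 95% interval -1.55 to -1.26) is a candidate explanation. Whether HNRNPU acts on these genes beyond DUX4 stays open, as DUX4 and HNRNPU fell in the same libraries.

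Repeat families were higher. In groups by name, formed after the values were seen, 36 of 40 Tigger, 36 of 40 Charlie and 72 of 88 L1M families rose. With repeats normalized among themselves 28, 24 and 54 rose and 2, 1 and 15 fell, and each group was higher than other families (camera adjusted p = 8.77e-05, 8.77e-05 and 4.82e-06 over 5 name groups). With an estimated correlation none was called (adjusted p = 0.0848 for each of the 3). L2 gave 6 of 7 higher and MIR 5 of 5 (3 of 5 among repeats, where its camera adjusted p was 0.095).

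More reads from introns could contribute to the rise of repeats, as 280 sense intronic genes had a median of 0.32 (0.15 to 0.51). Of the other annotation classes, 1490 lincRNA genes had a median of 0.21 (0.14 to 0.27), antisense genes 0.029, processed pseudogenes 0.0042 and protein-coding genes -0.036, so intronic genes were not the only class above 0.1. Reads from DNA cannot be told apart: counts over 404 olfactory receptor genes had a ratio of 1.15, between the bounds of 1.1 and 1.2 set for it, at 28.0 and 30.8 CPM against 25.7 and 25.3 in siNC (Poisson interval 1.09 to 1.22, counting error only). A scaling or composition cause stays open. Normalizing repeats among themselves gave 52.5% of calls higher but centres the families, and the raw share of repeats other than HERVH-int and LTR7, 3.06 percentage points higher in siHNRNPU, restates the rise and would also grow if RNA of genes fell.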
